A study of Mus musculus with 6 samples.

How the data were processed

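RNA of hematopoietic stem cells (HSCs), sorted from mouse by flow cytometry, was measured on 1-colour bead arrays. The labels place 3 arrays in a wild-type (WT) group and 3 in a GzmB-/- group, all from female C57BL/6 mice aged 12 weeks, and the series design gives each replicate as a pool of 3 mice. Per the labels' protocols, RNA was isolated with PicoPure columns, 2.5 ng was amplified with the NuGEN Ovation Pico whole-transcriptome kit and the product was biotin-labelled with an Encore module. Without technical repeats, variation from amplification cannot be separated from variation between pools.

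The deposited values are intensities on a linear scale, one column per array and one row per probe. The scale was read from the values themselves, which were all positive and had medians of 97.5 to 99.6 in every array. Column means were close together (160 to 163), and any scaling by the authors that made them so is not given in the sources used here. The sorted columns were not identical, so the table was not quantile normalized as it stands. No value was below 71.6, so the values hold either unsubtracted background or an added offset. A floor of this size compresses every fold change, most of all for dim probes. Scanner files and detection p-values were not used here. The rows may include control probes, which could not be identified from their identifiers, so all rows were kept in the percentiles, shares and tests.

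The table pairs its probes with Illumina probe identifiers and not with genes, and the reference table of mouse genes used here lists no such identifiers, so 0 probes could be given a gene name. This removed 3 planned results: the level of Gzmb itself (the check of the genotype labels), the tests of 37 gene lists, and the test of genes flanking Gzmb. The planned averaging of probes per gene was not run for the same reason. Chromosomal positions of probes are likewise not given here. The rule for named items, fixed before the data were examined, took in each direction the probes with the largest change among those past the threshold whose groups did not overlap and whose mean in at least 1 group was above the median of all probes, and filled up with the smallest unadjusted p. It was planned for 12 genes per direction and was held to 2 probe identifiers per direction because the identifiers carry no names.

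Intensities were put on the log2 scale and quantile normalized across the 6 arrays. All 46237 probes were fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes, with no covariate), GzmB-/- against WT, and the moderated test was two-sided with Benjamini-Hochberg adjustment over all probes. A probe was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9. Brighter probes are those whose mean over the 6 arrays was above the 75th percentile of all probes. A background limit per array was set after the values were seen, by reflecting the distance from the 1st percentile to the mode of the log2 intensities to the other side of the mode. Where every array of a group was under its limit, the fold is given as a lower bound against that limit.

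The fit was tested on simulated values for this comparison, with all 46237 probes, their fitted means and spreads drawn around their fitted variances. In each fold class 50 brighter probes were changed. The test recovered 34% of 1.5-fold changes, 80% of 2-fold changes, 94% of 3-fold changes and 96% of 4-fold changes at an adjusted p under 0.05, with 8 false calls. Changes of all classes were planted at once. With that many true changes the Benjamini-Hochberg cut is less strict than in the real data, where 3 probes passed. The simulated noise was also alike in all arrays. These shares are therefore likely too high for the real comparison. There ILMN_2597332, at a log2 change of -1.18, did not pass (limma adjusted p = 0.104). The precision of single values is limited by the number of arrays.

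Alternatives fixed before the data were examined were the deposited log2 values, a median shift, cyclic loess, an offset of 16 before log2, 2 filters on dim probes, trended and robust variance, array weights, the replicate number as a block, each array left out in turn, and a looser threshold (unadjusted p under 0.05 with at least 1.5-fold). Background correction by normexp on the intensities, with an offset of 16, was added after the data were seen. So was a fit without GzmB-/- replicate 3 with trended and robust variance. All 6 arrays carry one chip number in the labels, WT at positions A to C and GzmB-/- at D to F, so chip is no batch and chip position cannot be told apart from genotype.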

Results

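The study compared gene expression in HSCs, the rare bone marrow cells that regenerate all blood lineages, between mice lacking granzyme B and WT mice. Granzyme B, encoded by Gzmb, is a serine protease best known from the granules of cytotoxic lymphocytes, where it triggers apoptosis of target cells. The data were 6 arrays of 46237 probes, 3 per genotype, each from a pool of 3 mice. Between 35.9% and 40.0% of probes lay above the estimated background limit on each array (16599 to 18474 probes), and this share was 37.9%, 40.0% and 38.4% in the WT arrays and 36.4%, 38.8% and 35.9% in the GzmB-/- arrays. No probe could be assigned to a gene here and control probes could not be told from the rest, so the level of Gzmb in the GzmB-/- arrays was not analysed and transcripts are given by probe identifier.

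The first question was how far the genotypes differed across the transcriptome. Among the 11559 brighter probes (above the 75th percentile of the mean level), 86.6% differed by less than 1.2-fold between the group means and 99.4% by less than 1.5-fold, while 71 differed by 1.5-fold or more and 9 by 2-fold or more. The half-width of the 95% interval of a difference, not adjusted for the number of probes, had a median of 1.2-fold. Differences below about that size were therefore not resolved for a typical probe. The adjusted threshold is stricter, and in the simulation it recovered only 34% of 1.5-fold changes in brighter probes. These values held a floor of background or offset, which compresses folds. After normexp background correction, 69.98% of the same probes differed by less than 1.2-fold and 96.2% by less than 1.5-fold, 442 differed by 1.5-fold or more and 45 by 2-fold or more, and the median half-width of the interval widened to 1.33-fold. Across the brighter probes, without this correction, Pearson's r averaged 0.968 between WT arrays (0.967 to 0.970), 0.950 between GzmB-/- arrays (0.935 to 0.966) and 0.955 between arrays of different genotype (0.933 to 0.981). Probes are not independent replicates, and these r values describe the arrays only. The pair with the highest r, 0.981, was WT replicate 3 and GzmB-/- replicate 2. The mean r within genotypes exceeded that between them by 0.0039, which gave p = 0.1 in a one-sided exact permutation test over the 10 splits of the arrays, the smallest p these splits allow. This difference changed sign without WT replicate 1 (-0.0027) and without WT replicate 2 (-0.0011). Leaving out a WT array also leaves fewer WT pairs than GzmB-/- pairs in the mean within genotypes. Since r was lower between GzmB-/- arrays, the change of sign cannot be credited to the WT arrays left out.

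One GzmB-/- array stood apart from the rest. The first principal component of the brighter probes held 37.2% of the variance and placed GzmB-/- replicate 3 at 27.1, against -9.23 to -2.39 for the other 5 arrays. The second component held 24.1% and placed GzmB-/- replicate 1 at -21.0, against -0.60 to 8.74 for the others. The SD of an array's deviations from the mean of the other arrays was 0.304 on the log2 scale for GzmB-/- replicate 3, 0.244 for GzmB-/- replicate 1 and 0.161 for GzmB-/- replicate 2, compared with 0.190 to 0.215 in the WT arrays. The genotypes did not overlap on either component, which chance gives for 10% of such splits, but the gaps between them were small: WT arrays reached -5.46 and GzmB-/- arrays began at -3.53 on the first, and WT arrays reached down to 3.26 and GzmB-/- arrays up to 2.53 on the second.

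The second question was which transcripts differed between GzmB-/- and WT HSCs. In the limma test, 3 probes passed an adjusted p of 0.05, 2 higher and 1 lower in GzmB-/- HSCs. The transcript measured by ILMN_2418957 was 4.83-fold higher in GzmB-/- HSCs. Its normalized log2 intensity was 8.01 ± 0.27 (SD, n = 3) in WT and 10.28 ± 0.20 (SD, n = 3) in GzmB-/- arrays, a log2 change of 2.27 (SE 0.16, limma adjusted p = 0.0434). The normalized intensities were 213, 308 and 263 in the WT arrays and 1072, 1277 and 1418 in the GzmB-/- arrays. With an offset of 16 before log2 this probe did not pass (limma adjusted p = 0.0572).

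The transcript measured by ILMN_1220253 rose from the background. It lay under the background limit in every WT array, at 6.62 ± 0.02 (SD, n = 3), and reached 7.97 ± 0.07 (SD, n = 3) in GzmB-/- arrays. Its mean in GzmB-/- arrays was at least 2.41-fold higher than in WT arrays, with WT taken at the mean background limit. This bound was not itself tested. The limma adjusted p of 0.00202 belongs to the fitted log2 change of 1.35, with WT at its measured values. The transcript measured by ILMN_1254898 fell 2.18-fold in GzmB-/- HSCs. Its log2 intensity was 8.45 ± 0.02 (SD, n = 3) in WT and 7.32 ± 0.09 (SD, n = 3) in GzmB-/- arrays (log2 change -1.13, SE 0.06, limma adjusted p = 0.00947). ILMN_2747552, next in order among the lower probes, did not pass. It measured 8.18 ± 0.14 (SD, n = 3) in WT and 7.23 ± 0.06 (SD, n = 3) in GzmB-/- arrays, a log2 change of -0.95 (SE 0.08, limma adjusted p = 0.0787). Correcting the intensities for background by normexp raised the fold of ILMN_2418957 to 6.17, the fall of ILMN_1254898 to 3.02-fold and that of ILMN_2747552 to 2.67-fold, and the last then passed (limma adjusted p = 0.0112).

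With the ordinary variance model, each of the 3 calls was lost in at least 1 fit that left out a single array. Such fits have fewer arrays and so less power, and a lost call does not single out the array left out. ILMN_2418957 missed the threshold whichever array was left out, with limma adjusted p between 0.0736 and 0.33. ILMN_1220253 missed it without WT replicate 2 (limma adjusted p = 0.0515) or WT replicate 3 (0.0511). ILMN_1254898 missed it without WT replicate 1 (limma adjusted p = 0.152), WT replicate 2 (0.114), WT replicate 3 (0.175) or GzmB-/- replicate 2 (0.0788). Without GzmB-/- replicate 3, the array that stood apart, 1 probe was called higher and 1 lower. With trended and robust variance in that fit, chosen after the data were seen, all 3 probes passed (largest limma adjusted p 0.00231). That variance model was not run with any other array left out. With 1 array left out, the log2 change stayed between 2.14 and 2.40 for ILMN_2418957 and between -1.17 and -1.07 for ILMN_1254898. For ILMN_1220253 it stayed between 1.31 and 1.37.

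**Figure D1:**
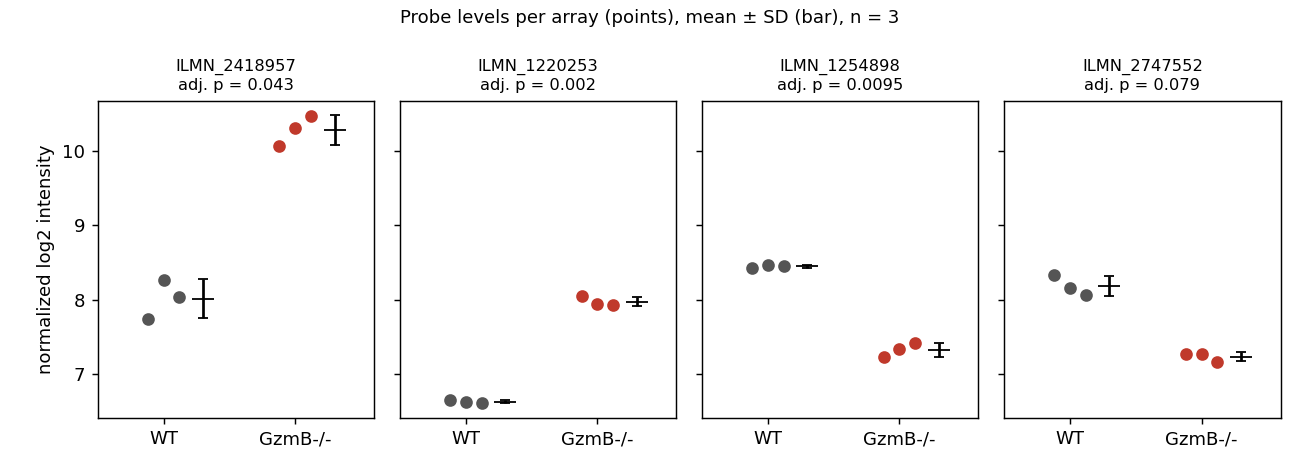
Normalized log2 intensity (vertical axis, quantile normalized) of the 4 named probes in each array (points), with the group mean and SD (horizontal mark and bar, n = 3), for WT and GzmB-/- HSCs. No value of one genotype overlaps the other, which the rule for named probes required. ILMN_2747552, at a limma adjusted p of 0.0787, did not pass.

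Beyond these probes the differences were smaller or less certain. At an unadjusted p under 0.05, 1222 probes were higher and 1533 lower in GzmB-/- HSCs, 2755 in all, where 2312 would be expected with no difference. The splits of the same 6 arrays that mix the genotypes gave 1589 to 2566 such probes. Leaving out 1 array gave 2001 (without WT replicate 1) to 3534 (without GzmB-/- replicate 2), and the count was under that expected without WT replicate 1 and without WT replicate 2 (2114). The groups did not overlap for 5286 probes, or 11.4%, against the 10% that chance gives for 3 arrays against 3. Mixed splits gave 3993 to 5124 such probes, and with 1 array left out the number was 0.998 to 1.21 times that expected by chance. A total of 60 probes combined an unadjusted p under 0.05 with a change of at least 1.5-fold, 40 of them higher and 20 lower, and 59 of the 60 were among the brighter probes. In 49 of the 60 the groups did not overlap. Thresholds on p and fold in these same data favour brighter probes and separate groups. Neither count was set against the mixed splits. Of the 40 higher probes, 3 were under the background limit in every WT array, whereas 0 of the 20 lower probes were under it in every GzmB-/- array. After normexp correction 312 probes were higher and 344 lower at the same thresholds, 656 in all, so neither the number nor the excess of higher probes was kept. Without GzmB-/- replicate 2 the counts were 125 higher and 50 lower, without WT replicate 3 they were 54 and 51, and without GzmB-/- replicate 3, the array that stood apart, they were 40 and 15.

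**Figure D2:**
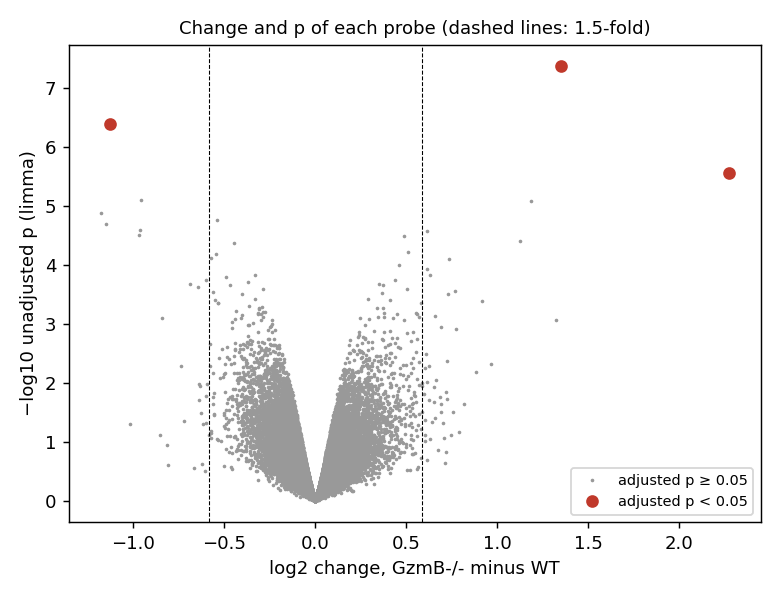
Each point is 1 of 46237 probes, with its log2 change (GzmB-/- minus WT, horizontal axis) and the −log10 of its unadjusted limma p (vertical axis). Red points mark the 3 probes with an adjusted p under 0.05, 2 to the right and 1 to the left of the dashed lines at 1.5-fold.

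With trended and robust variance in limma, 14 probes passed an adjusted p of 0.05, 8 higher and 6 lower. Restricting the test to the brighter probes gave 10 probes, 4 higher and 6 lower, and normexp correction gave 12, 6 in each direction. All 3 settings called 10 probes in common, including the 3 called above and ILMN_2747552.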

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

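The normexp correction and the fit without GzmB-/- replicate 3 under trended and robust variance were chosen after the data were seen. The 3 called probes remained called, with 2 higher and 1 lower, for the deposited log2 values, a median shift, cyclic loess and array weights. An offset of 16 left 1 higher and 1 lower, ILMN_2418957 then having an adjusted p of 0.0572 (limma; 8.82e-06 to 0.33 over all settings). Probes above the median level gave 3 higher and 3 lower, the brighter probes alone 4 and 6, trended and robust variance 8 and 6, normexp 6 and 6, and the looser threshold 40 and 20. Fewer probes enter the adjustment under the filters, but no cause of these counts was tested. Leaving out 1 array gave 0 to 2 higher and 0 to 1 lower probes; 0 were called without WT replicate 2, with 2114 at an unadjusted p under 0.05, and 0 without WT replicate 3, with 2876. Without GzmB-/- replicate 3 but with trended and robust variance, 12 were higher and 6 lower. The replicate block gave 0 higher and 0 lower (2818 at an unadjusted p under 0.05), the smallest adjusted p of the 3 probes being 0.0834; it leaves fewer residual degrees of freedom. The main fit was planned without this block because the series states no covariate. Same-numbered arrays did not deviate together (r across brighter probes 0.05, -0.12 and -0.04 for numbers 1, 2 and 3). The highest r between genotypes joined WT replicate 3 and GzmB-/- replicate 2 (0.15), and WT replicate 2 deviated most like GzmB-/- replicate 3 (0.06). These values gave no sign of pairing, but they were not the reason for leaving out the block. No log2 change of a named probe reversed. With an array left out this was fixed in advance, because the named probes were chosen for groups that do not overlap. The filters, the trended and robust variance and the replicate block could not reverse a change either, since they leave the difference of the group means as it is. The difference of correlations within and between genotypes ranged from -0.0027 to 0.0134 when 1 array was left out, reversing without WT replicate 1 (-0.0027) and without WT replicate 2 (-0.0011). The floor in the intensities limits the folds of dim probes. The Gzmb level, the gene lists, the genes flanking Gzmb and the averaging of probes per gene were not run because no probe carries a gene name here.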

Other observations

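The tests of chance splits, of normalization and of chip position below were chosen after the result was seen; the tests of probe pairs and of GzmB-/- replicate 3 were set down before their results. The 3 probes past the adjusted threshold were weighed first. All 3 kept their calls under the 3 other scalings of the arrays, with a smallest absolute log2 change of 1.11. The deposited values already held these changes, which argues against the quantile normalization applied here as their cause. The arrays had close medians and means as deposited, so the scalings had little to change. Any scaling by the authors before deposit was not tested. The call of ILMN_2418957 held only narrowly after the median shift (limma adjusted p = 0.0499). An offset of 16, not among these scalings, ended it (log2 change 2.20, limma adjusted p = 0.0572). Of the 10 splits of the 6 arrays, 1 gave as many called probes, the real one, with 3 against at most 0 in the others, and 10 splits are too few for a share under 0.05. The position on the chip cannot be told apart from genotype, since 0 of the position groups hold both genotypes. A difference in DNA around the targeted locus carried with the knockout allele stays untested, because no probe sequence or position was used here.

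Probes with consecutive numbers tended to behave alike, which gives a check that needs no gene names. Among 464 consecutive pairs of brighter probes, the mean levels correlated at r = 0.388 and the log2 changes between genotypes at r = 0.268, where the highest of 100 reshufflings of the pairs reached 0.115 and 0.0949. These correlations are across probes. Only 21 of the 60 probes changed by at least 1.5-fold had a consecutive partner. Of their 22 partners, 7 changed the same way at an unadjusted p under 0.05, or 31.8%, against a 95th percentile of 8.70% over 1000 random probe sets of like level. In 2 pairs both members were in the set of 60, and both pairs changed the same way, so these count on both sides. This argues against noise of single probes as the whole source of the differences in these 21 probes, and the other 39 were not tested. It does not separate an effect of genotype from differences between the pools of mice: 60 probes met the looser threshold in the real split and at most 37 in the others, and only 1 of 10 splits reached 60, with too few splits for a share under 0.05.

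GzmB-/- replicate 3 stood apart from the other arrays. After cyclic loess the SD of its deviations was still 1.49 times the median of the others, which argues against level-dependent scaling. Of its 70 brighter probes that deviated by over 1 on the log2 scale, 58 were higher (82.9%, exact 95% interval 72.0% to 90.8%). The interval treats probes of 1 array as independent and so may be too narrow. Higher probes also prevailed in GzmB-/- replicate 1 (15 higher, 3 lower) and WT replicate 1 (8 and 1). Few probes deviated so far in GzmB-/- replicate 2 (1 and 0), WT replicate 2 (1 and 3) and WT replicate 3 (0 and 3). An excess of higher probes was thus not particular to this array, and RNA of another cell type is neither shown nor excluded. The cells had been sorted by flow cytometry, but no measure of the purity of the sort was used here, and no marker gene could be looked up. Noise of single probes stays open too: deviations of consecutive pairs correlated at 0.158, above all 100 reshufflings (highest 0.111) but below the 0.19 to 0.31 seen in the other arrays. No biological explanation was tested.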
